A study of Mus musculus with 282 samples.

How the data were processed

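The deposited data were 282 transcriptomes of single hematopoietic stem cells (HSCs) from mouse bone marrow, each in its own well. The cells were sorted as LSK CD48-/lo CD150+, a gate in which LSK stands for lineage-negative, Sca-1-positive and Kit-positive. The mice carried 2 knocked-in alleles, a doxycycline-controlled transactivator at Rosa26 and a transgene at Col1a1 for histone H2B fused to GFP, and are labelled as not induced with doxycycline. Per the series description, 6 mice between 12 and 22 weeks old were used in 2 experiments. Per the labels' protocols, poly(A) RNA was reverse-transcribed with template switching, the cDNA was amplified with 22 PCR cycles, and 700 pg of cDNA went into tagmentation. No molecular identifiers were used, so reads from PCR copies are counted more than 1 time, and all binomial intervals and floors given here cover counting error only. Intervals on background levels come from 10000 draws of wells with replacement.

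The authors deposited 1 table of read counts per gene and cell. Per the submitters' processing notes, GSNAP (version 2018-07-04) and featureCounts (version 1.6.2) were used with the mouse build mm10, and the table's name gives Ensembl release 87 as annotation. How reads on several loci and the strand were handled is not given in the sources used here. Genes with near-identical copies (H2, Gimap, Ifitm, Serpina3, Lyz, Ctla2 and oxphos families with pseudogenes) and overlapping or antisense genes are therefore uncertain. Of 49764 rows, 49671 were Ensembl genes, 92 were ERCC spike-in RNAs and 1 was the H2B-GFP transgene, 1116 bp long. The spike-in rows held 11.7% of all counts and, with the transgene row, stayed out of totals and tests. Symbols were found for 49326 of the 49671 identifiers. Coordinates are those of the deposited table, in mm10, counted from 1.

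All cells carried 1 condition and formed 1 group. The labels name a library number and an HSC code for each cell. Library numbers begin with 29 or 32, and the 2 library series crossed with the codes give 6 sets, named here L29 HSC-3, L29 HSC-4 and L32 HSC-2 to L32 HSC-5. The labels do not say what the code stands for or which mouse a cell came from. The group is thus 1 sample as far as animals are named, so the sets are not known to be independent animals. P-values over sets measure only the spread between sets, which may be technical, and effect sizes with the number of sets sharing a sign are given first.

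Cells with at least 100000 gene counts and at least 1000 genes were kept, 232 of 282. A stricter filter of 3 median absolute deviations kept 222. CPM values (counts scaled to 1 common total per cell) were computed from the deposited counts of the Ensembl genes, and values were taken as log2(CPM/10 + 1). A gene was called detected in a cell at 10 CPM, which in the median kept cell is 2.8 reads. No doublet caller was run, since each well received 1 sorted cell. No 2 cells had identical counts.

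Before the data were examined, 22 gene lists with 370 entries (363 different genes) were fixed, as were the tests, the thresholds and the rule for the genes to be named. All 370 entries were found in the table, 1 of them through an older symbol. The lists cover HSC identity, long-term HSC (LT-HSC), S phase, G2/M, quiescence, G0 exit, growth, oxidative phosphorylation (oxphos), lysosome and autophagy, immediate early, interferon, MHC, Gimap, sex-linked, megakaryocyte, erythroid, myeloid, B cell, T and NK cell, mast cell and basophil, endothelium and stroma, and multipotent and lymphoid progenitor genes. The naming rule took all HSC identity genes and the 4 members of every other list with the highest mean CPM for detection. For a score it took the 10 genes per direction with the largest mean z past an adjusted p of 0.05 and with 1 sign in 6 of 6 sets, plus the 4 members with the largest mean z of each list past the list test. It took the 25 genes with the largest excess variance, the 10 per direction with the largest fold for the library series, the 10 with the smallest p for the codes, the 5 per direction with the smallest p for the plates, and the sex-linked genes in every set. Genes without a symbol, predicted genes and pseudogenes are counted, not named. Some genes that the rule takes are not reported here.

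Shares of cells carry exact Clopper-Pearson 95% intervals, or an SD over the 6 sets. A share of 0 allows up to 3 cells of the total. A score was the mean log value of a list. For each gene and set, a partial Spearman correlation with a score was computed across cells, given the ranks of genes detected and total counts and the plate, with the gene itself left out of the score. The Fisher z values of the 6 sets were tested against 0 in limma, with weights by cells per set and a variance moderated across genes, so that its SE of the mean z differed little between the named genes (0.0694 to 0.0757), and the mean rho given is their weighted mean turned back from z, with Benjamini-Hochberg adjustment over 9689 genes at 10 CPM in at least 10% of cells. Lists were tested on the z values with camera at a preset correlation of 0.01, and again with an estimated correlation. Shuffling a score among the cells of a set and plate 100 times gave the count expected by chance. Relations between scores used an exact two-sided sign-flip test over 6 sets, whose smallest possible p is 0.03125.

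Variance above a lowess trend on the mean (span 0.3, over the same 9689 genes) was computed per set after removing plate means. Leiden clustering at resolution 0.5 used a graph of 15 nearest neighbours on 20 principal components of 2000 variable genes, after set and plate means were removed. Library series, codes and plates were compared on counts summed over kept cells with edgeR's quasi-likelihood test (TMM normalization, filterByExpr, Benjamini-Hochberg adjustment). The codes and plates were planned on 8 sums, but no cell of code HSC-2 on plate 2 of L32 was kept, so 7 were used. Wells in which over 50% of reads were spike-in, called near-empty below, gave a background level. Their CPM values give the make-up of background reads and not the amount of background RNA in a kept cell. Each well received 1 sorted cell, so part of these reads may come from a poorly captured cell, which was not tested.

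Tools were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, scran 1.30.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and leidenalg 0.10.2. The score associations, the variance above the trend and the tests on sums were tested on simulated data, and the other steps were not. With 100 genes made to follow the score at each slope and a count dispersion of 2, the score step recovered 37% of genes at a log slope of 0.5 and 99% at 1, with 5 false calls among 9689. At a dispersion of 8 it recovered 0% at either slope. Both dispersions were set and not estimated from the cells, so the power of the score step in these data is not known. The tests on sums had almost no power. At the fitted spread, they recovered 0% of 2-fold and 0% of 4-fold changes between library series, 0% and 7% between codes, and 2% and 6% between plates. With the spread reduced to 0.1 times the fitted one, a simulation added later, they recovered 35% and 68% between series, 18% and 42% between codes, and 23% and 61% between plates. The variance step found 10% and 47% of genes given an added log SD of 1 and 2 in all 6 sets when overdispersed counts were simulated, and 96% and 100% with counting noise only.

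Alternatives fixed beforehand were other detection thresholds, thinning of each cell to 190267 reads (208 cells, 24 shallower ones left out), no cell filter, the stricter filter, log2(CPM + 1), scran size factors, Pearson correlation, fewer covariates, other units and gene filters, RLE normalization, DESeq2 and leaving out each set or sum. Alternatives added after seeing the data were leaving out L29 HSC-4 for the counts that had no such planned setting, G2/M calls without Smc4, counts adjusted over a list alone without each set for the library series, scores scaled to spike-in reads, and gene reads per spike-in read plus mitochondrial share as added covariates. The 4 relations of scores with RNA content were also added after seeing the data. The 50 wells under the cell filter were left out of all comparisons and used only for the background and the transgene row.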

Results

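Single HSCs from adult mice were profiled to describe the transcriptome of the LSK CD48-/lo CD150+ compartment, in a series whose title concerns mitotic activity of primitive HSCs. The animals carried the H2B-GFP label-retention alleles without doxycycline, so all cells belonged to 1 untreated group. Of 282 cells, 232 were kept. Kept cells had a median of 280096 gene counts (range 116009 to 1680710) and 5222 genes. The sets L29 HSC-3, L29 HSC-4, L32 HSC-2, L32 HSC-3, L32 HSC-4 and L32 HSC-5 held 46, 43, 22, 44, 38 and 39 kept cells, with median totals of 286194, 210973, 350054, 273444, 266542 and 297206. Set L29 HSC-4 stood apart, with a median of 4151 genes against 5126 to 5686 in the other sets and a mitochondrial share of 6.66% against 3.28% to 3.73%. All 23 wells of code HSC-2 and 20 of 40 wells of code HSC-3 on plate 2 of L32 fell under the filter. All of these lay in odd-numbered columns of the plate, which lost 43 of 47 wells against 0 of 47 in even-numbered ones, and for HSC-3 20 of 24 against 0 of 16.

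The first question was which HSC and lineage genes the sorted cells carried. All 26 HSC identity genes were at 10 CPM in at least 10% of cells, and 14 were in at least 50%. Angpt1, which encodes angiopoietin-1 (chromosome 15, 42424727 to 42676977), was detected in 92.7% ± 3.1 of cells (SD, n = 6 sets) at a mean of 728 CPM, the transcription factor Meis1 at 89.6% ± 12.6 and the receptor Kit at 85.2% ± 7.1. The transcription factors Hlf and Mecom stood at 74.6% ± 7.1 and 60.6% ± 7.3, and Procr, which encodes the surface marker EPCR, at 56.7% ± 21.4. Slamf1, which encodes the sorting marker CD150, was at 10 CPM in 19.7% ± 4.3 of cells. Cd48, which the gate excludes at high levels, reached it in 0.862% of cells. Background was measured in 38 near-empty wells with 616795 gene reads, 22 of L32 HSC-2 and 16 of L32 HSC-3, all in these odd-numbered columns, and could not be measured in the other 4 sets. Levels set against it are sums over the 66 kept cells of the same 2 sets. There Angpt1 had 76.2 against 764 CPM and Procr 107 against 298 CPM. Lmo2 (1067 against 445 CPM), Esam (668 against 254 CPM), Itga6, Erg and Tek were higher than in the kept cells. Near-empty wells held fewer gene reads than spike-in reads. Kept cells of L32 HSC-2 and L32 HSC-3 had medians of 13.9 and 17.4 gene reads per spike-in read. CPM compares the make-up of the reads and not the amount of RNA. It thus does not tell how much background added to the shares of these 5 genes.

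**Figure D1:**
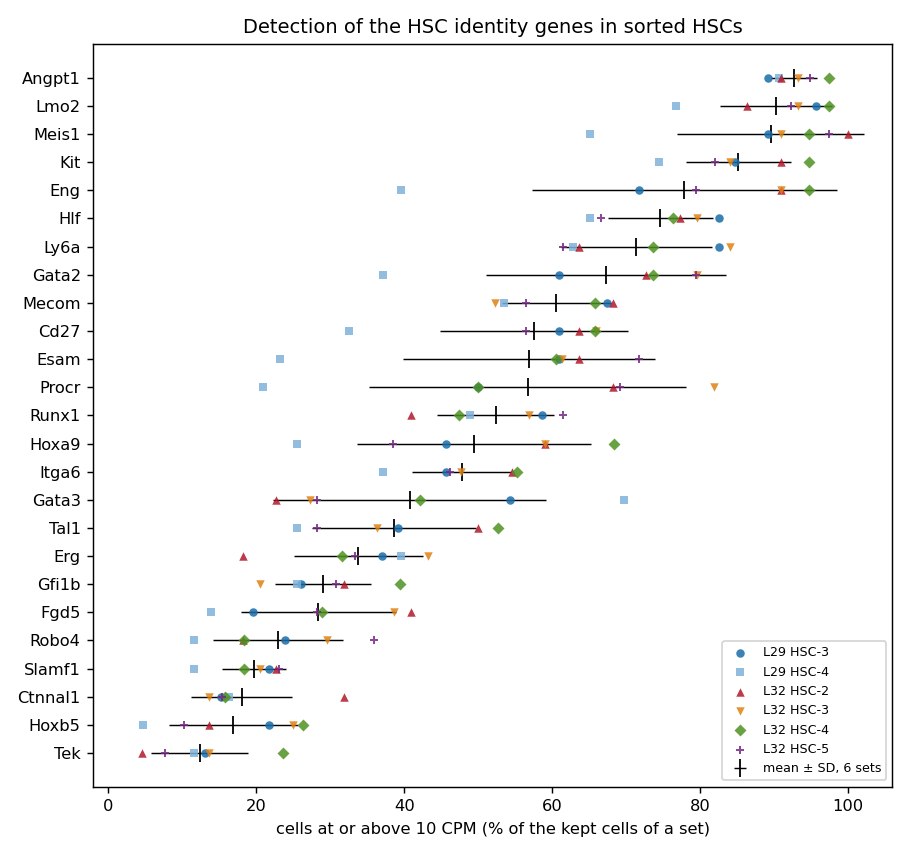
Share of kept cells at or above 10 CPM (x axis, percent) for 25 HSC identity genes (y axis), with 1 point per set and a bar for the mean ± SD of 6 sets. Angpt1 lies at or above 89.1% in every set, and L29 HSC-4 is the lowest set for Meis1, Eng and Esam.

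Genes of mature blood lineages were mostly undetected, with a few exceptions. Of 16 myeloid genes, only Lyz2 (lysozyme) and Prtn3 (proteinase 3) reached 10% of cells, at 87.2% ± 11.7 and 82.3% ± 12.7 (SD, n = 6 sets), while Mpo was at 1.72% and Elane was in 0 of 232 cells, which allows up to 1.29%. Of 16 erythroid genes, 3 reached 10%, led by carbonic anhydrase Car2 at 96.4% ± 3.5 and followed by the globin genes Hbb-bt at 12.7% ± 5.1 and Hbb-bs at 11.1% ± 4.7. In the near-empty wells Lyz2 had 97.3 CPM against 481 CPM in kept cells of the same 2 sets, Prtn3 68.1 against 492 and Car2 501 against 1567. None of 10 T and NK cell genes and none of 8 mast cell and basophil genes reached 10%, the highest being Nkg7 at 7.76% and Cpa3 at 3.02%. Of 9 B cell genes only Cd79b passed, at 25.6% ± 7.9, and of 12 endothelial and stromal genes only Emcn, at 28.9% ± 10.7, and Col1a2, at 14.8% ± 10.8. Of 18 megakaryocyte genes 13 reached 10%, with Mmrn1 at 66.7% ± 23.4, Cd9 at 70.2% ± 12.6 and Vwf, which encodes von Willebrand factor, at 27.6% ± 8.6. Of 14 multipotent and lymphoid progenitor genes 4 passed, with Cd34 at 49.8% ± 8.9, Flt3 at 10.7% ± 6.7 and Mef2c at 61.6% ± 8.3, the last at 1187 CPM in near-empty wells against 196 CPM in kept cells of the same sets.

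Among the functional lists, 22 of 22 oxphos genes, 23 of 24 growth genes and 17 of 18 lysosome and autophagy genes were at 10 CPM in at least 10% of cells. The nucleolar genes Npm1 and Ncl were in 98.8% ± 1.9 and 91.3% ± 8.8 of cells (SD, n = 6 sets), and Atp5b, a subunit of ATP synthase, was in 95.0% ± 6.6. All 10 MHC genes reached 10%, with B2m in 100% of cells, as did 11 of 14 interferon genes and 6 of 8 Gimap genes. Of 29 LT-HSC genes 20 passed, with Ifitm1 in 100% of cells, although it was higher in near-empty wells (4275 CPM) than in kept cells of the same sets (2608 CPM). Quiescence genes passed in 11 of 18 cases. Txnip, a thioredoxin-binding protein, was in 98.5% ± 2.8 and Ndn, which encodes necdin, in 40.2% ± 11.3, whereas Cdkn1a was in 2.59% and Cdkn1c in 8.19%. The G0 exit list passed with 8 of 10 genes, led by Ccnd2 at 93.9% ± 8.9 and Cdk4 at 83.6% ± 9.2. Immediate early genes passed in 9 of 22 cases, with Ier2 at 49.6% ± 13.0 and Fos at 2.16%. Of the genes named here, Ncl (1438 against 1089 CPM), B2m and Cdk4 (576 against 552 CPM) were also higher in near-empty wells than in kept cells of the same sets. Ndn was about as high (159 against 176 CPM). These CPM values do not tell how much background added to the shares of these genes. In all, 210 of 363 list genes reached 10% of cells, and 214 did without L29 HSC-4. Of the 210, 32 were higher in near-empty wells than in kept cells of the same sets, among them 8 of the 22 oxphos, 3 of the 23 growth and 0 of the 17 lysosome and autophagy genes counted above. Whether background lifted any of these genes past 10% of cells was not measured.

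The title's question of mitotic activity was approached by counting cells with transcripts of G2/M genes. Of 232 cells, 13 carried at least 5 of 30 G2/M genes at 10 CPM, 5.60% (exact Clopper-Pearson 95% interval 3.02% to 9.39%). The sets gave 5.21% ± 3.71 (SD, n = 6), with 0 of 22 cells in L32 HSC-2, which allows up to 13.6% by the 3-cell floor and 15.4% by the exact interval, and 4 of 38, 10.5%, in L32 HSC-4. The intervals of all 6 sets overlapped. In these 13 cells the DNA topoisomerase Top2a was detected in 9, Ckap2 in 9, the mitotic kinase Cdk1 in 8, the survivin gene Birc5 in 7 and Mki67 in 5. Smc4 was in all 13 and in 62.5% of all cells, and it was at 418 CPM in near-empty wells against 122 CPM in kept cells of the same sets. Without Smc4 the share was 3.88%, 9 cells. Over all cells Top2a was in 12.5%, Cdk1 in 9.91% and Mki67 in 5.60%. Of the 13 cells, 12 also carried at least 5 of 31 S-phase genes, as did 145 of all 232 cells, 62.5%, and no cycling was read from the S-phase genes. Mcm6, a subunit of the replicative helicase, was in 57.9% ± 10.3, and 22 of 31 S-phase but only 4 of 30 G2/M genes reached 10% of cells. The share is a range of a count and not a type, since 46 cells held 3 or 4 G2/M genes and 7 held 5 or 6. It was 25.4% at a minimum of 3 genes, 1.72% at 10 genes and 17.7% at 1 CPM, and after thinning to 1 depth, with 1 read as detection, 14.9% of 208 cells.

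**Figure D2:**
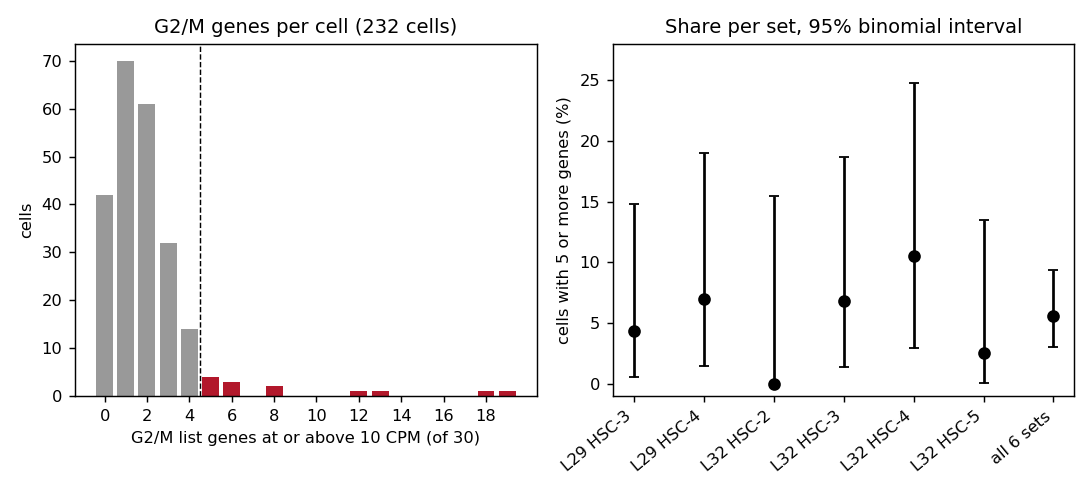
Left, number of cells (y axis) by the number of G2/M list genes at or above 10 CPM (x axis), with cells at 5 or more in red. Right, share of cells with 5 or more genes (y axis, percent) per set and pooled, with exact Clopper-Pearson 95% intervals. The pooled share is 5.60% of 232 cells.

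Genes associated with the cell cycle score, the mean of the S-phase and G2/M genes, were sought within each set. Cells with a higher score had more of the replication genes Hells (mean rho 0.378 ± 0.091, SD over n = 6 sets), Prim1, the primase (0.366 ± 0.219), Lig1, a DNA ligase (0.364 ± 0.082), the licensing factor Cdt1 (0.316 ± 0.199) and Mcm2 (0.312 ± 0.080). Fignl1, Fam111a, Cdca7 and Casp8ap2 were also among the 10 leading genes, and each of the 10 had a positive sign in 6 of 6 sets. Of the genes named, Hells, Mcm2 and Cdca7 are members of the score, each left out of it for its own rho. Hells lies on chromosome 19 (38930915 to 38971051) and Lig1 on chromosome 7 (13277283 to 13311433). Txnip had the opposite sign in 6 of 6 sets (mean rho -0.334 ± 0.131). The adjusted p in limma was 0.00125 for Hells and Lig1 and 0.00587 for Txnip. In all, 40 of 9689 genes passed an adjusted p of 0.05, 37 positive and 3 negative, and at most 1 gene did in 100 shuffles of the score. Besides Txnip, the negative genes were Slc34a2 (-0.305 ± 0.243) and A430010J10Rik (-0.279 ± 0.230), each negative in 5 of 6 sets and named after their values were seen. Of the 26 tested members of the score itself, 24 were positive and 12 passed. Of the 10 leading genes, Casp8ap2 and Fam111a were higher in near-empty wells than in kept cells of the same sets, as were 9 of the 37 positive genes and 2 of the 3 negative ones, Slc34a2 and A430010J10Rik. Because the score is built from S-phase and G2/M genes, replication genes following it, members or not, are not independent evidence of cycling.

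By list, growth genes (19 of 23 positive, median rho 0.087), oxphos genes (16 of 22, median 0.078) and G0 exit genes (7 of 8, median 0.089) lay above other genes, and LT-HSC (4 of 20 positive, median -0.086), lysosome and autophagy (5 of 17), MHC (2 of 10) and Gimap genes (0 of 6) lay below, in camera at a preset correlation. The adjusted p values ran from 9.04e-05 for LT-HSC to 0.0218 for MHC. None of these 7 calls held with an estimated correlation, where the lowest adjusted p was 0.168. Adjusted over the list alone, 3 growth genes (Nhp2, Gnl3 and Nop58) and 1 oxphos gene (Uqcrq) were positive, and 1 LT-HSC gene (Ltb), 3 lysosome and autophagy genes (Map1lc3b, Sqstm1 and Gabarapl1) and 1 quiescence gene (Txnip) were negative. Over all genes tested, only Txnip of these passed. The largest members were Nhp2 (mean rho 0.257 ± 0.221, adjusted p = 0.0762 in limma) and Gnl3 of growth, Uqcrq (0.262 ± 0.102, 0.0534) of oxphos, Cdk4 of G0 exit, Ltb (-0.217 ± 0.078) of LT-HSC, Map1lc3b (-0.208 ± 0.164) of lysosome and autophagy, Gimap5 and H2-K1. Cdk4, Gimap5 (428 against 168 CPM) and Nop58 were higher in near-empty wells than in kept cells of the same sets. The HSC identity, immediate early, interferon, megakaryocyte and quiescence lists did not pass (adjusted p 0.317 to 0.748), and the median and the mean differed in sign for all of these but interferon.

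The count of 40 depended on single sets. It was 9 without L29 HSC-3, 27 without L29 HSC-4, 17 without L32 HSC-2, 9 without L32 HSC-3, 7 without L32 HSC-4 and 24 without L32 HSC-5. With only the plate as covariate 1427 genes passed, and with RNA content and mitochondrial share added 9 did, all positive. Txnip lost its call with the latter (mean rho -0.275, adjusted p = 0.0988 in limma, against 0.000113 to 0.0503 under the other alternatives) and without L32 HSC-5 (-0.293, 0.0503).

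The LT-HSC score was built from 29 genes of long-term repopulating cells. Cells with a higher score had more Procr itself (mean rho 0.369 ± 0.078 with Procr left out of the score, SD over n = 6 sets), the focal adhesion gene Tns2 (0.357 ± 0.140), Mllt3 (0.351 ± 0.185), the lysosomal protease Ctsb (0.350 ± 0.154), Txnip (0.321 ± 0.120), Gimap3 (0.310 ± 0.137), Pdzk1ip1, Net1, St8sia4 and the quiescence gene Ndn (0.284 ± 0.078). They had less of Ctla2a (-0.358 ± 0.159), the pyrophosphatase Dctpp1 (-0.345 ± 0.094), the cytokine Mif (-0.344 ± 0.080), Txn1, which encodes thioredoxin (-0.329 ± 0.116), the complex IV subunit Cox6c (-0.320 ± 0.185), Nme1 (-0.320 ± 0.099), Sh2d5, Atpif1, Polr2l and the ADP/ATP carrier Slc25a5 (-0.293 ± 0.155). All 20 had 1 sign in 6 of 6 sets. Procr lies on chromosome 2 (155751117 to 155755471), Txnip on chromosome 3 (96557957 to 96561883) and Mif on chromosome 10 (75859353 to 75860250). The adjusted p in limma was 0.00139 for Procr, Tns2, Mllt3, Ctsb, Ctla2a, Dctpp1 and Mif. In all, 79 of 9689 genes passed, 37 positive and 42 negative, and at most 1 did in 100 shuffles. Besides Procr, the score members Mllt3 and Pdzk1ip1 were among the leading positive genes, each left out of the score for its own rho. All 20 tested members of the score were positive and 6 passed. Of these members, Fads3 (1388 against 23.7 CPM), Pdzk1ip1 (1242 against 495 CPM) and Ifitm1 were higher in near-empty wells than in kept cells of the same sets. So were 9 of the 10 leading negative genes, all but Sh2d5 (Cox6c at 1326 against 223 CPM, Mif at 175 against 160 CPM), and 21 of the 42 negative but 6 of the 37 positive genes, against 2063 of all 9689 genes tested.

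**Figure D3:**
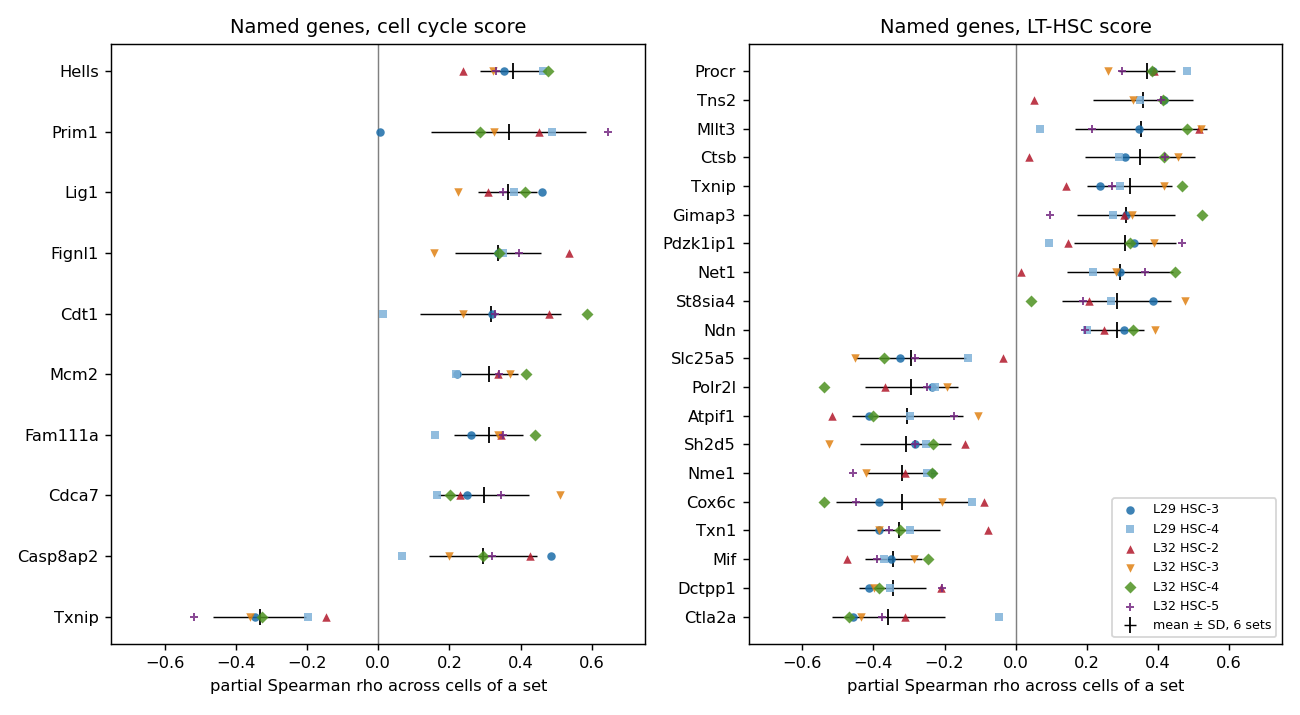
Partial Spearman rho (x axis) of the named genes (y axis) with the cell cycle score (left) and the LT-HSC score (right), with 1 point per set and a bar for the mean ± SD of 6 sets. Every point of the leading positive genes shown lies above 0, and those of Txnip lie below 0 for the cell cycle score and above 0 for the LT-HSC score.

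Lists moved along the LT-HSC score in both directions. S-phase genes (0 of 22 positive, median rho -0.140), growth genes (5 of 23 positive, median -0.123) and oxphos genes (5 of 22 positive, median -0.067) lay below other genes, and lysosome and autophagy genes lay above (15 of 17 positive, median 0.111). The adjusted p in camera was 6.06e-09 for S phase, 1.51e-07 for growth, 0.000265 for oxphos and 1.95e-05 for lysosome and autophagy, and with an estimated correlation each of the 4 held at an adjusted p of 0.0442. HSC identity (18 of 24 positive), interferon (10 of 11), MHC (6 of 10), megakaryocyte (9 of 12) and immediate early genes (8 of 9) lay above at the preset correlation, with adjusted p from 0.000265 to 0.0125. With an estimated correlation these 5 calls were lost at adjusted p = 0.107 for HSC identity and megakaryocyte, 0.13 for interferon and MHC and 0.0975 for immediate early. G0 exit and quiescence did not pass (adjusted p = 0.244 each), and for quiescence the median rho (-0.042) and the mean (0.033) differed in sign. Among members, the polyamine enzyme Srm (-0.283 ± 0.276), the co-chaperonin Hspe1 (-0.276 ± 0.150) and Uqcrq (-0.265 ± 0.219) were negative, and Eng (0.268 ± 0.120), H2-K1 (0.287 ± 0.209) and H2-D1 (0.250 ± 0.118) were positive past an adjusted p of 0.05 in limma. Adjusted over the list alone, 9 growth, 3 oxphos and 2 S-phase genes were lower and 2 lysosome and autophagy, 3 HSC identity, 4 MHC, 1 interferon, 1 megakaryocyte and 2 quiescence genes were higher, against 2, 2, 0, 1, 2, 2, 0, 1 and 2 over all genes tested. The 2 S-phase genes were Chaf1b (-0.217 ± 0.248, adjusted p = 0.138 over all genes in limma) and Pcna (-0.213 ± 0.214, 0.135).

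The count of 79 was 22 without L29 HSC-3, 82 without L29 HSC-4, 69 without L32 HSC-2, 20 without L32 HSC-3, 37 without L32 HSC-4 and 43 without L32 HSC-5. With only the plate as covariate it was 41, and with the stricter cell filter 35.

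The LT-HSC score was then set against 6 other list scores across the cells of each set. It was lower in cells with a higher cell cycle score (mean rho -0.168 ± 0.127, mean Pearson r -0.281, SD over n = 6 sets), growth score (-0.282 ± 0.160, r -0.334) and oxphos score (-0.202 ± 0.108, r -0.253), and higher with the immediate early score (0.235 ± 0.086, r 0.226). Each of these 4 had 1 sign in 6 of 6 sets for rho and for r, and each exact two-sided sign-flip test gave p = 0.03125, the smallest that 6 sets allow. Adjusted over the 6 pairs, p was 0.0469 for rho and 0.0375 for r. The megakaryocyte score (0.184 ± 0.154, 5 of 6 sets positive, r 0.203) and the multipotent and lymphoid progenitor score (-0.181 ± 0.140, 5 of 6 negative) did not pass (exact p = 0.0625 each). For the latter r was -0.246, negative in 6 of 6 sets with an adjusted exact p = 0.0375.

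The calls of the 3 negative relations rested on few cells. Without the 2 cells of each set farthest from the median of the LT-HSC score, rho was -0.114, -0.222 and -0.126 and r -0.195, -0.246 and -0.137, each negative in 5 of 6 sets (exact p for r 0.0625, 0.0938 and 0.188). For the immediate early score rho was then 0.224 and r 0.233, positive in 6 of 6 sets (exact p = 0.03125, adjusted 0.0938 and 0.0625). With only the plate as covariate the 3 negative relations were negative in 5 of 6 sets and did not pass. Nor did they with values scaled to spike-in reads (rho -0.027, -0.151 and -0.056, adjusted exact p = 0.531, 0.188 and 0.531) or with RNA content and mitochondrial share added (-0.127, -0.248 and -0.124, adjusted exact p = 0.0938, 0.15 and 0.219).

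**Figure D4:**
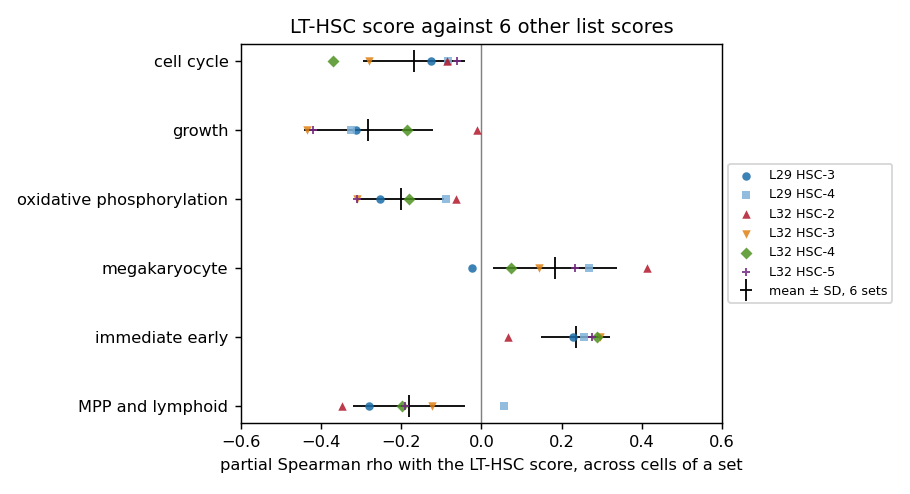
Partial Spearman rho between the LT-HSC score and 6 other list scores (y axis) across the cells of a set (x axis), with 1 point per set and a bar for the mean ± SD of 6 sets. The cell cycle, growth and oxphos points all lie below 0 and the immediate early points all lie above 0.

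The genes that varied most between cells were ranked by variance above the trend on the mean. Hspa5, a chaperone of the endoplasmic reticulum, led (excess 4.05 ± 1.05, SD over n = 6 sets, on the squared log2 scale), with Xbp1 (3.20 ± 1.38), P4hb (3.02 ± 0.96), Rpn2, Stt3a and Pdia6 also among the 25 named genes. Hspa5 lies on chromosome 2 (34771970 to 34777547). Adgrl4, an adhesion receptor, stood second (3.37 ± 0.61), and the transcription factors Myc (2.94 ± 0.72) and Mycn (2.89 ± 1.03), the chaperonin subunits Cct7 and Cct8, the mitochondrial genes mt-Cytb and mt-Co1, the antigen presentation genes B2m and H2-Aa, the helicase subunit Mcm6 (2.78 ± 1.08), and Serpina3g, Gimap6, Slfn2, Arl6ip1, Nedd4, Tsc22d3, Cd164, Tnfaip8 and Muc13 made up the rest. Of the 25, only B2m was higher in near-empty wells than in kept cells of the same sets. The genes mt-Cytb, mt-Co1 and B2m were in 100% of cells, at means of 10850, 10829 and 8680 CPM. At such levels log2(CPM/10 + 1) and log2(CPM + 1) differ by almost a constant, so the variance is nearly the same on both. Yet their excess was 3.26, 3.22 and 2.87 on the first scale and 8.03, 8.04 and 7.28 on the second. Their rank thus rests on the fitted trend at the highest means, and they are not shown to vary more than other genes. In all, 1978 of 9689 genes lay above the trend in 6 of 6 sets. Of the lists, 8 of 10 MHC, 15 of 26 HSC identity, 13 of 22 S-phase and 8 of 23 growth genes tested did so, and 0 of 22 oxphos genes did. No test was made, since cells are not replicates.

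Clustering after removal of set and plate means gave 3 clusters of 134, 74 and 24 cells. The smallest, 10.3% of cells, was led by S-phase genes. Mcm3 was detected in 95.8% of its cells against 31.7% of the others, Mcm2 in 87.5% against 20.2% and Lig1 in 87.5% against 15.9%. It had cells in all 6 sets, from 5.13% of L32 HSC-5 to 16.3% of L29 HSC-4. Procr was in 29.2% of its cells against 58.7% and Mllt3 in 45.8% against 65.9%. The cluster of 134 cells had more of Wdr43, Atxn10 and Xbp1. The cluster of 74 cells had fewer genes per cell (median 4466 against 5390 and 6414) and less of the chaperonin genes Tcp1 and Cct3, Cdca7 and Paics. The first principal component, with 3.86% of the variance, had a rho of 0.752 with genes detected, which the clustering did not hold fixed. The split into 134 and 74 cells may thus follow genes detected, which was not tested. No cluster was led by markers of another blood lineage, and none was named as a cell type. By mean log2 difference over list genes, the cluster of 24 cells was higher for S phase (2.97), growth (1.08) and multipotent and lymphoid progenitor genes (0.83). It was also higher for Cd79b, the 1 B cell gene tested (0.88), and lower for LT-HSC genes (-0.54). At resolution 1.0 there were 5 clusters, with 20 of the 24 cells of the smallest in a cluster of 22. With 1000 genes and 10 components 23 of the 24 lay in a cluster of 43, and without L29 HSC-4 there were 2 clusters, with 17 of 17 remaining cells in one of 115.

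Library series L32 was compared with L29 to measure the difference between experiments or batches, which the labels do not separate. Both L29 sets, L32 HSC-4 and L32 HSC-5 carried Xist in most cells, while L32 HSC-2 and L32 HSC-3 carried Y-linked transcripts. The comparison is thus mixed with the apparent sex of the sets. No gene of 16476 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test on 4 against 2 summed sets, 1433 had an unadjusted p under 0.05, and DESeq2 called 410 genes, 299 higher and 111 lower in L32. HSC identity genes had a median log2 difference of 0.43, MHC genes 0.54, myeloid genes -1.37 and oxphos genes -0.38, and these were 0.28, 0.59, -2.13 and -0.11 without L29 HSC-4 and 0.52, 0.66, -1.19 and -0.60 without L29 HSC-3. Adjusted over the list alone, 6 of 10 MHC genes passed, 5 higher and 1 lower in L32, as did Psap and Gimap1 (higher) and Fos, Csf1r and Ebf1 (lower) of 5 other lists, against 0 over all genes tested. H2-D1 had a log2 difference of 0.60 ± 0.14 (SE, adjusted p = 0.369 over all genes in edgeR), and B2m one of -0.36 ± 0.09 (0.387). Set L29 HSC-4, 1 of the 2 L29 sums, had the lowest share of cells with H2-K1, H2-D1 and H2-T23, and without it 1 MHC gene passed over the list alone (H2-Ab1, higher in L32), against 2 without L29 HSC-3 (B2m and H2-Ab1) and 5 or 6 without each L32 set in turn. Without L29 HSC-3, 4 of 22 oxphos genes were lower over the list alone (Ndufa1, Ndufa2, Ndufa4 and Cox6c) and 4 of 18 quiescence genes higher (Rbl2, Txnip, Rarb and Tcf15), against 0 of either with all sets, and the quiescence median went from 0.36 to 1.26. A lone L29 sum is taken there to vary like the L32 sums. Each of the 5 calls of other lists was lost without at least 1 set, that of Ebf1 also without L29 HSC-4, where 23.3% of cells carried it against at most 2.27% elsewhere. Genes in this paragraph are named after their values were seen.

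The 4 HSC codes within L32 were compared on 7 sums, and no gene of 17428 passed in edgeR's quasi-likelihood test (632 unadjusted, 228 in DESeq2). Codes HSC-2 and HSC-3 carried Y-linked transcripts and HSC-4 and HSC-5 carried Xist, so the codes too are mixed with apparent sex. The 10 genes with the smallest p, each at an adjusted p of 0.841, included Thbs1, which encodes thrombospondin-1, Vldlr, Eif2s3y, Serpina3f, Hspa5, Rasgef1b, Sgcb, Itih5 and Slc31a2. All 10 passed with DESeq2 (adjusted p from 7.17e-27 for Eif2s3y to 0.0129 for Hspa5). Thbs1 was at 275 CPM in the sum of code HSC-4 on plate 1 and at most 0.562 CPM in the other 6 sums. Hspa5 was at 454 and 458 CPM in the sums of HSC-4 against 744 to 1143 CPM in the other 5. All 5 sex-linked genes passed when adjusted over the list alone. Plate 2 against plate 1, with the code as a block, gave 0 of 17428 genes (611 unadjusted, 203 in DESeq2).

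Sex-linked genes divided the sets. Xist, the X-inactivation RNA, was at 10 CPM in 82.6%, 60.5%, 86.8% and 76.9% of the cells of L29 HSC-3, L29 HSC-4, L32 HSC-4 and L32 HSC-5, against 0% and 4.55% in L32 HSC-2 and L32 HSC-3. The Y-linked translation factor gene Eif2s3y was in 72.7% and 52.3% of cells of L32 HSC-2 and L32 HSC-3 and in 0% of the other 4 sets. Ddx3y was in 40.9% and 27.3%, Uty in 13.6% and 18.2% and Kdm5d in 13.6% and 11.4% of those 2 sets, with 2.63% as the highest share of any of the 3 elsewhere. The near-empty wells, all of these same 2 sets, carried more CPM of 3 of the 4 Y-linked genes than the kept cells of these sets (409 against 212 for Eif2s3y) and less of Kdm5d (8.11 against 14.1). Xist was at 22.7 CPM in these wells against 1.6 CPM in the kept cells of the same sets.

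**Figure D5:**
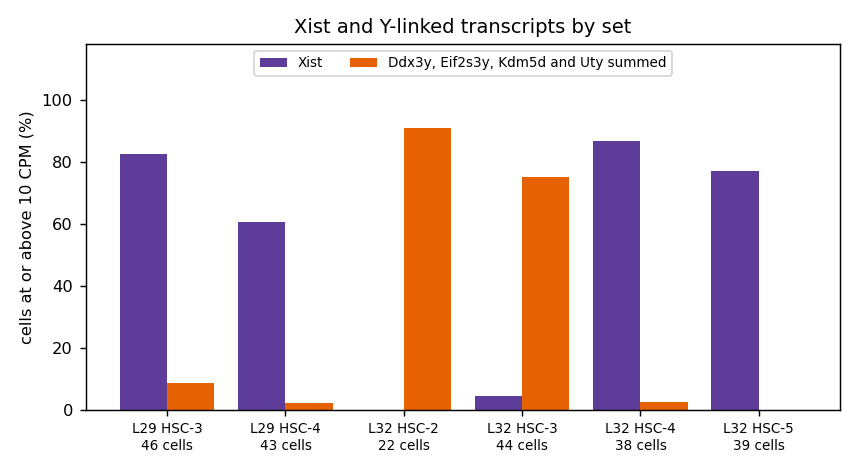
Share of kept cells (y axis, percent) at or above 10 CPM for Xist (purple) and for the sum of 4 Y-linked genes (orange) in each of the 6 sets (x axis, with the number of cells). Y-linked transcripts are in 90.9% and 75% of the cells of L32 HSC-2 and L32 HSC-3 and in at most 8.7% of the cells of the other sets.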

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

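The tests on H2B-GFP reads from outside the cell, on Lyz2, Prtn3 and Car2, and on spike-in scaling and RNA content were chosen only after the result was seen.

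A signal appeared in the row of the transgene, which enters no comparison of the report. At least 1 H2B-GFP read was found in 19 of 232 kept cells without doxycycline, 8.19% (exact 95% interval 5.00% to 12.5%), above the 1.29% that a count of 0 allows. Of these, 3 cells held 126, 61 and 22 reads and 16 held 1 to 3. Reads from outside the cell may account for the low counts, since 7 of 50 left-out wells also held reads, at a pooled 8.48 CPM (95% interval over resampled wells 2.42 to 17.6) against 0.256 (0.133 to 0.406) in kept cells with fewer than 10 reads. Exchange of index sequences from the 3 wells was not supported but stays open. Wells in their rows and columns held 1 to 9 reads in 1 of 52 cases against 10 of 133 elsewhere on these plates (one-sided Fisher exact p = 0.977), too few to exclude it. The 3 cells with 22 or more reads are not covered by either test, that their animals had not been induced rests on the labels alone, and no biological explanation was tested.

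Lyz2, Prtn3 and Car2 were in over 80% of cells sorted as HSCs. For L32 HSC-2 and L32 HSC-3, the values argue against free RNA or carry-over as the source of Lyz2 and Prtn3. In near-empty wells these genes were at 20.2% and 13.8% of the CPM of the kept cells of the same 2 sets (upper limits over resampled wells 40.2% and 35.0%, under 50%). Reads of Lyz2 and Prtn3 came from 13 and 4 of the 38 near-empty wells, and the other sets had no such wells. For Car2 the ratio was 32.0% with an upper limit of 74.4%, so by CPM alone a large part from free RNA would stay open. The ratio leaves out the amount of RNA. Near-empty wells held fewer gene reads than spike-in reads. Kept cells of L32 HSC-2 and L32 HSC-3 had medians of 13.9 and 17.4 gene reads per spike-in read. Less RNA at a lower Car2 CPM argues against free RNA as the source of a large part of Car2 in these 2 sets. Mature myeloid or erythroid cells would bring S100a8, S100a9, Ngp, Camp, Ltf, Hba-a1, Hbb-bs, Hbb-bt and Alas2, whose highest mean was 2.57% of the Lyz2 CPM, for Hbb-bt. The source of the 3 transcripts stays open, since near-identical copies of these genes and transcript uptake were not tested.

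The LT-HSC score was negatively related to the cell cycle, growth and oxphos scores. Scaling to spike-in reads, in place of total reads, left a highest mean rho of -0.027 among the 3 pairs, with 4, 5 and 4 of 6 sets negative. With RNA content and mitochondrial share as added covariates the highest was -0.124, with 6, 4 and 5 of 6 sets negative. Spike-in scaling divides both scores' genes in a cell by the same spike-in count, so an error in that count moves both scores the same way. A weaker negative rho under it thus cannot show that CPM scaling is a source. Neither value lies at 0 or above, and neither keeps 5 of 6 negative sets in each pair. It stays open whether part of the relation comes from scaling or RNA content. Whether all of it does cannot be told apart with 6 sets, and the biological alternative was not tested. Whether free RNA in the wells contributes cannot be told. By CPM, 21 of the 42 genes negative with the LT-HSC score were higher in near-empty wells than in kept cells, against 21.3% of all genes tested. Of the S-phase, growth and oxphos genes at 10 CPM in at least 10% of cells, 0 of 22, 3 of 23 and 8 of 22 were. CPM does not give the amount of free RNA in a kept cell, and the near-empty wells came from L32 HSC-2 and L32 HSC-3 only.

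Among 229 groups of 6 sets tested for a set far from the rest, 27 held one. At 1 in 20, 11.5 would be expected by chance for independent groups of normal values. These groups share the same cells, so 11.5 is only a rough guide. For Ifitm3, H2-K1 and H2-D1 all other sets stood at 100%, so a few cells set the flag. Set L29 HSC-4 accounted for 20 of the 27. It had a median of 4151 genes and a mitochondrial share of 6.66%. It was lowest in the share of cells with Gimap9 (16.3%), Ncl (74.4%), Ldha (74.4%), Meis1 (65.1%), Esam (23.3%), Cd27 (32.6%), Ifitm3 (97.7%), Map1lc3b (76.7%), Gabarapl1 (41.9%), Mmrn1 (20.9%), H2-K1 (95.3%), H2-D1 (95.3%), H2-T23 (72.1%), Atp5a1 (72.1%), Cox4i1 (88.4%) and Txnip (93.0%). It was highest for Ebf1 (23.3%, against at most 2.27% elsewhere), and its rho of Ctla2a with the LT-HSC score was -0.048. L32 HSC-2 was highest for Pdgfrb (9.09%) and Ctnnal1 (31.8%), and its LT-HSC score had the lowest rho with the immediate early score (0.066), with Tns2 (0.052) and, in size, with Txn1 (-0.077). L32 HSC-3 had a rho of -0.525 for Sh2d5 with the LT-HSC score, and L29 HSC-3 had a median spike-in share of 3.32%.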

How the results depend on the processing

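Alternatives without L29 HSC-4 (outside the leave-one-out ones), without Smc4, with spike-in scaling and with RNA content and mitochondrial share added were chosen after seeing the data, as were counts over a list alone without each set. The count of list genes in over 10% of cells stayed between 207 and 234, and the number of genes above the variance trend in all sets between 1780 and 2443. Of 25 named variable genes, 19 to 25 were again among the first 25. No named gene and no relation reversed its direction past a threshold. The cause was not tested for any change below unless stated. G2/M shares of 5.60% became 25.4% (3 genes), 1.72% (10 genes), 17.7% (1 CPM) and 14.9% (thinned), 8.51% without the cell filter, 5.29% without L29 HSC-4 and 3.88% without Smc4, the threshold setting the value.

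The 40 genes of the cell cycle score became 1427 with the plate only (40 shared), 190 with Pearson (34 shared), 20 with log2(CPM + 1), 23 with 9 units of series, code and plate, 11 with the stricter filter, 21 of 4453 genes in 30% of cells, and 9 with RNA content and mitochondrial share added. Leaving out each set gave 7 to 27. The 79 genes of the LT-HSC score became 41 with the plate only and 35 with the stricter filter (35 shared), 63 with RNA content and mitochondrial share added (50 shared), and 20 to 82 leaving out each set. They rose to 111 with Pearson (65 shared) and to 105 of 4453 genes in 30% of cells (62 shared). Lists past the threshold went from 7 to 0 for the cell cycle score and from 9 to 4 for the LT-HSC score with an estimated correlation.

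The 3 negative relations kept their call with Pearson, log2(CPM + 1), scran, the stricter filter and 9 units (9 of 9 negative in each, adjusted exact p = 0.00781). The 9 units are the 6 sets with L32 HSC-3, HSC-4 and HSC-5 split by plate. They are not known to be more independent than the 6 sets, so their lower p carries no added weight. Under other settings relations lost their adjusted call, keeping their sign in the mean. For the cell cycle, growth and oxphos scores rho was -0.141, -0.197 and -0.170 with the plate only, -0.114, -0.222 and -0.126 without the 2 farthest cells, -0.027, -0.151 and -0.056 scaled to spike-in reads, and -0.127, -0.248 and -0.124 with RNA content and mitochondrial share added. The immediate early relation was 0.262 with the plate only, 0.189 with 9 units (6 of 9 positive), 0.224 without the farthest cells, 0.245 scaled to spike-in reads and 0.235 with RNA content added, with adjusted exact p from 0.0938 to 0.145. For 3 of these 5 settings its own exact p stayed 0.03125, and the adjusted value rose because other pairs had larger p. The multipotent and lymphoid progenitor relation passed with Pearson (-0.246) and log2(CPM + 1) (-0.160). Leaving out a set (smallest possible p 0.0625) and 4 units (0.125) allow no call and say nothing of stability.

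Clusters went from 3 to 5 at resolution 1.0, were 3 with 1000 genes and 10 components (largest 44.4% against 57.8% of cells, and 23 of the 24 cells of the smallest in one of 43) and were 2 without L29 HSC-4. The tests on sums went from 0 genes to 410 (series), 228 (codes) and 203 (plate) with DESeq2, and to 2 for the series without the low-count filter. They stayed at 0 with RLE and thinned sums, for the series without each L32 set and for the plates without each sum. The self-test covered only the full sums with TMM, where it shows almost no power, and these alternatives were not simulated. Of 436 shares of named genes, 64 moved by over 1 SD (30 without the cell filter, 22 at 1 CPM, 12 thinned), and all 25 variance values moved with log2(CPM + 1), another scale. For mt-Cytb, mt-Co1 and B2m the change of scale leaves the variance nearly unchanged, so the fitted trend moved. Named genes and lists were counted together over all settings. For the cell cycle score 40 calls were lost, 14 gained and 570 values unchanged, and 85, 9 and 753 for the LT-HSC score. Genes and lists without a call at the main setting count as unchanged where they stayed without one. Of the called named genes, all 11 of the cell cycle score and all 27 of the LT-HSC score kept their call with scran size factors. Without L32 HSC-4, 5 of the 11 kept it, and without L32 HSC-3, 12 of the 27. With 10 CPM worth 2.8 reads in the median cell, genes below that level could not be told from absence.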

Other observations

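The tests on RNA content, sex-linked genes and plates were chosen only after the result was seen.

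RNA content, as gene reads per spike-in read, was higher in cells with higher cell cycle, growth and oxphos scores within every set. With the plate as covariate, mean rho was 0.541 ± 0.128 for the cell cycle score (mean Pearson r 0.521), 0.563 ± 0.192 for growth (0.519) and 0.531 ± 0.140 for oxphos (0.500), SD over n = 6 sets and positive in 6 of 6 (exact two-sided sign-flip p = 0.03125 for rho and r, 0.0417 adjusted over 4 relations). Without the 2 farthest cells of each set r was 0.521, 0.552 and 0.515. For the LT-HSC score rho was -0.135 ± 0.339, positive in 1 of 6 sets (exact p = 0.344, r -0.180). Genes detected per cell and depth were not held fixed here. Cells with more reads per spike-in read may show more genes above a threshold, which was not tested. Median gene reads per spike-in read were 29.1 in L29 HSC-3 and 13.9 to 17.4 in the other 5 sets.

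Of the 3 cells with 22 or more H2B-GFP reads, the cell with 126 reads ranked 1 of 46 in its set by LT-HSC score and 35 of 46 by cell cycle score. The cell with 61 reads ranked 4 of 43 and 17 of 43, and the cell with 22 reads ranked 25 of 39 and 22 of 39. With 3 cells no test was made.

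Between library series the gene with the smallest p in edgeR was a ribosomal RNA gene, CT010467.1, at 8417 ± 825 CPM in L29 and 2040 ± 559 CPM in L32 (SD over 2 and 4 sets, log2 difference -1.98 ± 0.22 SE). Pkm, which encodes pyruvate kinase, was at 213 ± 25 against 466 ± 30 CPM and Lcp1, which encodes L-plastin, at 429 ± 1.45 against 789 ± 76 CPM. These 3 genes are named after their values were seen, and none passed (adjusted p = 0.340).

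A hypothesis from Xist and the Y-linked genes is that each set holds cells of animals of 1 sex, L32 HSC-2 and L32 HSC-3 male and the other 4 female, which the labels do not state. If sets mixed the sexes evenly, both kinds of transcript would be common in a set. The lower of the 2 shares was at most 8.70%, in L29 HSC-3, where all 4 cells with Y-linked reads also carried Xist. A small share of cells from the other sex cannot be excluded, and near-empty wells of L32 HSC-2 and L32 HSC-3 held Xist at 22.7 CPM against 1.6 CPM in the kept cells there.

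For the 0 genes between plates, 32 of 32 fitted splits of the 7 sums into 3 and 4 gave at least as many, as any split must against a count of 0. The highest other split also gave 0, and the count of splits says nothing about chance.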
